A study of Mus musculus with 2 samples.

How the data were processed

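H3K4me1 was measured by chromatin immunoprecipitation with sequencing in pooled hearts of mouse embryos (strain B6NCrl) at embryonic day 10.5. The labels give 2 biological replicates of 1 group, with 69 embryos in replicate 1 and 51 in replicate 2, both of mixed sex, and replicate numbers were taken from them. The deposited data used here were 4 peak lists in narrowPeak format on build mm10. Per the file headers and readmes, each replicate list derives from the alignments of that replicate and a control, the pooled list from the alignments of both replicates and both controls, and the replicated list from the other lists. The peak caller, its version, the aligner and the rule for a replicated peak are not given in the sources used here. Read depth is not given either, so no interval that needs it was computed, and 1 value per replicate is the only measure of biological spread.

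The authors deposited for every peak a signal value, the caller's own measure of enrichment over the control, whose scale the readmes do not state, and a −log10 p-value and −log10 q-value. The smallest deposited −log10 p was 2.03, so the lists reach down to weak peaks. The authors also deposited a display score of the narrowPeak format, whose values run to 1000 within each list and whose scaling is not given in the sources used here, and it was not used. Signal values served to rank or describe peaks within a list, and to compare ranks across peaks that both replicate lists touched. Peaks within a list did not overlap. The analysis covered the 19 autosomes and chromosome X, which left out 1 peak on an unplaced contig from the pooled list and 1 from the replicate 1 list. Chromosome Y held no peak in any list. All columns of per-sample values in the files were assigned to a sample.

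Gene models came from the GENCODE M21 basic annotation of the same build, and sequence from the matching reference genome. For each of 21728 protein-coding genes with a unique symbol the 5′-most TSS was used. Other annotated starts were left out, so peaks at them count as distal. Peak overlap required at least 1 bp. Chance overlap was measured with 100 circular shifts of one list within chromosomes. Peak midpoints were assigned, in this order, to promoters (within 2 kb of a protein-coding TSS), exons, introns or intergenic sequence, and their shares were divided by the share of known sequence in each class. TSSs were called CpG-rich where the observed over expected CpG ratio within 500 bp either side was at least 0.6.

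The coverage of a gene is the percent of the window from 50 kb upstream to 50 kb downstream of its TSS covered by peaks. The median of each of 21 gene lists fixed before the data were examined, 10 of them of heart lineages, was compared with 100000 random lists of the same size, matched on quintile of the number of TSSs in the window. This two-sided permutation test treats genes as the units and describes these samples. Genes are not replicates, neighbouring genes share windows, and some genes stand in 2 lists. All list genes were found in the annotation. The share of list genes with a peak within 2 kb of the TSS, and the share whose TSS lay in a long domain, were compared with the other protein-coding genes by Fisher's exact test, two-sided. The exact tests were matched on neither gene density nor GC content. Domains were peaks merged across gaps of up to 3 kb, and the longest 5% were called long. P-values were adjusted by Benjamini-Hochberg over the lists, with a threshold of 0.05.

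Motifs were searched in peaks over 2 kb from the 5′-most TSS of every protein-coding gene. Windows of 100 bp either side of the deposited summit were searched on both strands for 20 consensus sequences. The sequences were fixed before the data were examined, 12 for heart factors and 8 for other tissues. The background was as many random windows outside the pooled peaks, matched on chromosome and on GC in bins of 2 percent, compared by Fisher's exact test with adjustment over the motifs. A consensus match is not evidence of binding.

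The genes named were fixed by rule before the data were examined. They were Nkx2-5, Gata4, Tbx5, Hand2, Myh6, Myh7, Tnnt2 and Nppa, the 3 most covered genes of each heart list, the most and the least covered gene of each other list, the genes with a TSS in the 10 longest domains, the 10 genes with the largest gap between the replicates, and the nearest genes of the 10 peaks with the highest signal. Where a list held several genes at 0, the last in the order of the list was taken. Other genes overlapped by a long domain or a strong peak are named to place it.

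The alternatives were stricter −log10 q limits of 2 and 5, overlaps of 50%, equal numbers of top peaks, the pooled list, each replicate list alone, promoter windows of 1 and 5 kb, coverage windows of 10 and 100 kb, unmatched random lists, peak numbers in place of coverage, merging gaps of 1 and 12.5 kb, the longest 10% of domains, motif windows of 250 bp either side, a background 5 kb from each peak, and the 25% of distal peaks with the highest signal. After the data were examined, random lists matched on GC, lists without chromosome X, 1 gene per set of overlapping windows, direct differences between lists, motif windows free of repeats and a background 5 kb away matched on GC were added.

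The procedures were tested on simulated data. A copy of the replicate 1 list with a known share left in place gave an overlap of 61.3%, equal to the count by bedtools. With window coverage shuffled among the 21728 genes, the list test at p below the threshold called 5.0% of 200 lists of 20 genes without a change, 51.5% of those with coverage multiplied by 2 and 82.0% with coverage multiplied by 3. Fisher's exact test called 0.50% of 200 lists with the same share as other genes and 100.0% of those in which every gene had a peak. A motif planted in a known share of 20000 windows was found in 10.4% of them. This equals the share expected from planting and matches by chance together, and no other motif was called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1, bedtools 2.31.1 and matplotlib 3.10.9 were used.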

Results

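Chromatin immunoprecipitation with sequencing for H3K4me1, the monomethylated form of lysine 4 of histone H3 that marks enhancers and the flanks of promoters, was carried out on hearts of mouse embryos at embryonic day 10.5. At this stage the looped heart tube holds beating myocardium, an endocardial lining, and the forming cushions and epicardium. The samples formed 1 group of 2 biological replicates, each a pool of hearts from embryos of both sexes, 69 embryos for replicate 1 and 51 for replicate 2. The labels name no treatment, genotype or second tissue, so the comparisons that follow are between the replicates, between parts of the genome, and between gene lists fixed before the data were examined. Sequencing depth was not given in the sources used here, so the precision of each list rests on the peak caller's own scores and on the spread between the replicates.

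H3K4me1 peaks covered a small part of the genome in many short stretches. The list of replicated peaks held 155546 peaks on genome build mm10, with a median length of 721 bp, and covered 155.4 Mb, which is 6.07% of the known sequence of the autosomes and chromosome X. The list called on the pooled replicates was longer, with 268672 peaks over 190.4 Mb. Replicate 1 gave 252076 peaks with a median length of 304 bp, covering 113.2 Mb, and replicate 2 gave 222855 peaks with a median length of 359 bp, covering 122.4 Mb. Many replicate peaks were weak. A −log10 q of at least 5 was reached by 21.3% of replicate 1 peaks and 36.2% of replicate 2 peaks, against 81.4% of replicated peaks. The longest single peak spanned 44362 bp.

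The replicates marked largely the same regions. A peak of the other replicate overlapped 68.2% of replicate 1 peaks by at least 1 bp (95% Wilson interval 68.0 to 68.4) and 69.5% of replicate 2 peaks (69.3 to 69.7), where the intervals cover counting error only. Circular shifts of one list along the chromosomes, run 100 times, gave a mean of 7.88% for replicate 1 and 8.43% for replicate 2, and at most 8.47% and 9.02%. The Jaccard index of the covered base pairs was 0.487, against a mean of 0.0240 after shifting. Requiring an overlap of 50% of both peaks lowered the shared share to 35.6% of replicate 1 peaks and 40.3% of replicate 2 peaks. Across the 123322 replicated peaks that both replicate lists touched, the signal values of the replicates had a Spearman rho of 0.527, with peaks as the units and not independent replicates. The 25% of these peaks with the highest signal in replicate 1 were in the highest 25% of replicate 2 in 60.2% of cases. For genes, the measure was the percent of the window reaching 50 kb either side of the transcription start site (TSS) that peaks covered. It had a Spearman rho of 0.985 between the replicates across 21728 protein-coding genes, those with little or no coverage included. This rho and that of the signal values differ in measure and in the set compared, so they do not rank agreement by scale.

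Most of the mark lay away from the 5′-most TSS of genes, mainly in introns. Of the replicated peaks, 85.6% lay over 2 kb from the 5′-most TSS of every protein-coding gene. Peaks at other annotated starts of a gene count as distal here. By the position of the peak midpoint, 54.9% of replicated peaks were in introns, 26.4% between genes, 12.7% within 2 kb of a protein-coding TSS and 5.92% in exons. Relative to the share of the genome in each class, promoter windows held 4.03 times as many peak midpoints, exons 1.67 times and introns 1.31 times, while intergenic sequence held 0.514 times as many. The promoter ratio was 3.89 in the replicate 1 list and 3.83 in the replicate 2 list, and the intergenic ratio was 0.504 and 0.5001. With a promoter window of 5 kb the promoter ratio fell to 2.63.

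Around TSSs in CpG-rich sequence H3K4me1 peaks were most frequent downstream of the start site, whereas at CpG-poor TSSs they were most frequent at or close to it. At the 10061 CpG-rich TSSs, a replicated peak covered the start site in 29.8% of genes, the position 1100 bp downstream in 56.6% and the position 600 bp upstream in 38.6%. The highest downstream share was 1.90 times the share at the start site. At the 11667 CpG-poor TSSs the profile was highest at the start site, at 27.7%, and the same ratio was 0.997. The class is that of the 5′-most TSS alone, so a gene with a CpG-rich start further downstream can stand among the CpG-poor ones. The replicates differed in the depth of the dip at CpG-rich TSSs. A peak covered 27.1% of these start sites in replicate 1 and 15.7% in replicate 2, and the ratio of the downstream flank to the start site was 1.53 in replicate 1 and 2.95 in replicate 2. An upstream rise was present in replicate 2, with 29.6% at 600 bp upstream, but not in replicate 1, whose highest upstream share was 27.4%, at 100 bp. At CpG-poor TSSs the replicates gave 21.8% and 21.5%. With 1 value per replicate this gap has no test against replicate error.

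**Figure D1:**
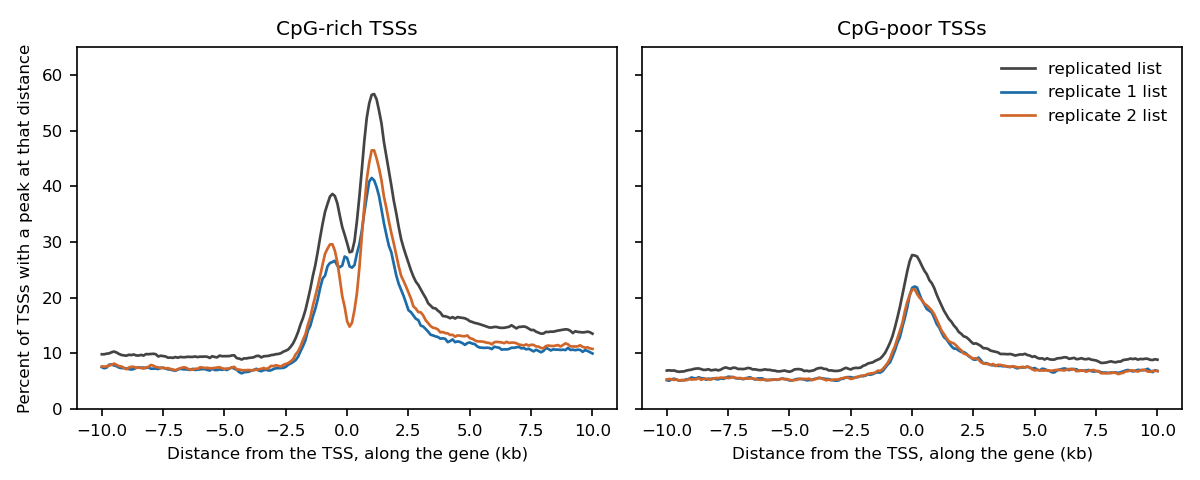
Percent of protein-coding TSSs with an H3K4me1 peak (vertical axis) at each distance from the TSS in kb along the direction of the gene (horizontal axis), for CpG-rich TSSs (left) and CpG-poor TSSs (right), in the replicated list (grey), the replicate 1 list (blue) and the replicate 2 list (orange). At CpG-rich TSSs the replicated list rises to 56.6% downstream and dips to 29.8% at the TSS, and the dip is deeper in replicate 2 than in replicate 1. At CpG-poor TSSs all 3 lists are highest at or close to the TSS.

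Genes of the heart muscle had more H3K4me1 around them than random genes. The median protein-coding gene had 6.80% of its window covered by replicated peaks (interquartile range 1.29 to 16.6), and 3907 genes had no replicated peak in the window. Cardiac transcription factors had a median of 30.0% (22 genes), against 4.31% for random lists of the same size and gene density. Sarcomere genes had a median of 32.3% (23 genes, random lists 6.93%). Genes of conduction, calcium handling and natriuretic peptides had 23.5% (20 genes, random lists 5.37%). Signalling genes of heart development had 18.3% (21 genes, random lists 4.69%). Each of the 4 medians lay above the random medians in two-sided permutation tests with 100000 random lists. The permutation p was 2e-05 for transcription factors and for sarcomere genes, the smallest these permutations can give. The adjusted permutation p was 1.4e-04 for these lists, 2.1e-04 for conduction genes and 9.24e-04 for signalling genes, with Benjamini-Hochberg adjustment over 21 lists. In the replicate 1 and replicate 2 lists taken alone, the medians were 20.3% and 24.5% for transcription factors, 23.3% and 23.5% for sarcomere genes, 15.2% and 19.0% for conduction genes and 12.8% and 14.4% for signalling genes, and all 4 lists passed the test in each. The call for signalling genes was lost when the random lists were matched on the GC content of the window in place of gene density (permutation test, adjusted p = 0.0947, with a range of 1.05e-04 to 0.0947 over 12 alternatives).

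**Figure D2:**
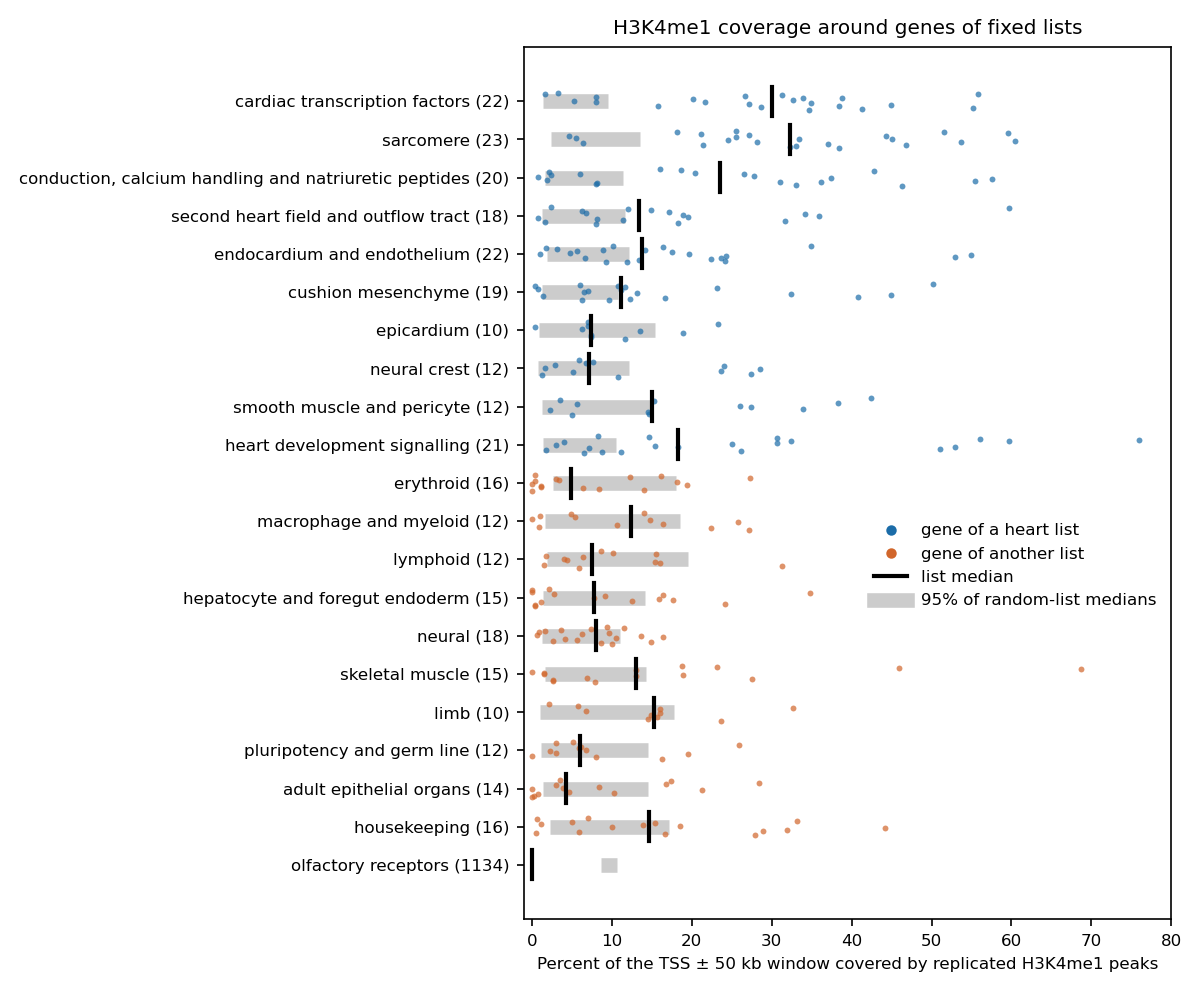
Percent of the window of 50 kb either side of the TSS covered by replicated H3K4me1 peaks (horizontal axis) for the genes of each fixed list (rows, number of genes in parentheses). Points are genes, black bars list medians, and grey bars the range holding 95% of the medians of random lists of the same size matched on gene density. Single olfactory receptor genes are not drawn. The medians of sarcomere genes (32.3%) and cardiac transcription factors (30.0%) lie far to the right of the grey bars, and that of olfactory receptors is 0.

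Of the 22 cardiac transcription factors, 16 lay above the 75th percentile of all genes and 3 below the median. Nkx2-5, a homeodomain factor required for heart looping, lies on chromosome 17 (26838664 to 26845009, minus strand). Its window was 34.7% covered by 32 replicated peaks, and the replicate lists covered 26.2% ± 0.441 (SD, n = 2). Gata4, a zinc finger factor of the early myocardium, lies on chromosome 14 (63198922 to 63271692, minus strand) and had 41.3% covered, with 32.0% ± 1.23 in the replicate lists (SD, n = 2). Tbx5, a T-box factor of the atria and left ventricle, had 38.5% covered and 30.1% ± 0.931 in the replicate lists (SD, n = 2). Hand2, a basic helix-loop-helix factor of the right ventricle and outflow tract, had 21.7% covered, with 14.1% in replicate 1 and 18.3% in replicate 2, and no replicated peak within 2 kb of its TSS. The most covered genes of the list were Tead1 at 55.8%, Gata5 at 55.2% and Tbx2, a repressor of chamber genes in the atrioventricular canal, at 45.0%.

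**Figure D3:**
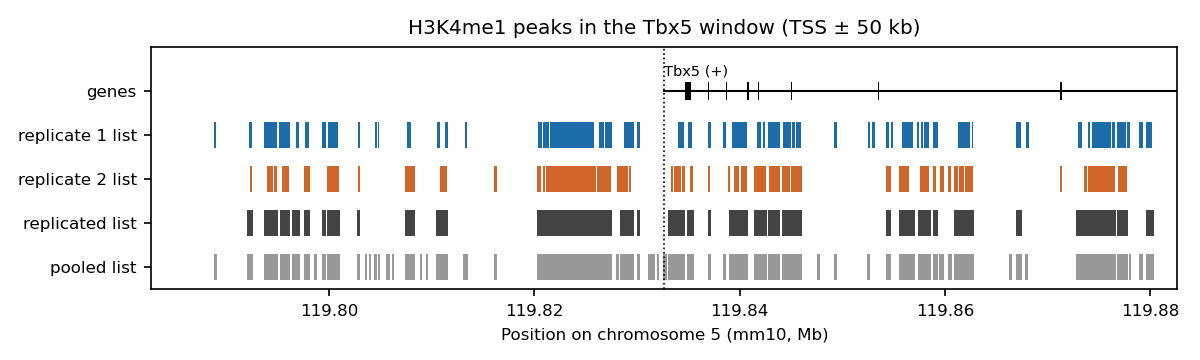
Map of the Tbx5 window on chromosome 5 (mm10, position in Mb on the horizontal axis), with Tbx5 exons as black boxes, its TSS as a dotted line, and the peaks of each list as coloured boxes, 1 row per list. Replicated peaks, 29 of them, cover 38.5% of the window, both upstream of the TSS and within the gene, and the lists of both replicates mark the same clusters of peaks.

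Among the 23 sarcomere genes, 20 lay above the 75th percentile of all genes and 3 below the median. Tnni1, the slow troponin I of the embryonic heart, had 60.4% of its window covered, Tcap, which encodes telethonin of the Z-disc, had 59.6% and Tnnt2, cardiac troponin T, had 53.7%. The windows of Tnni1 and Tnnt2 overlap on chromosome 1. Myh6, the alpha myosin heavy chain, had 38.4% covered and its neighbour on chromosome 14, Myh7, the beta chain, 32.3%. With 1 gene kept for each set of overlapping windows, a comparison added after the data were examined, the 4 lists kept their calls. In the conduction and calcium list 12 of 20 genes lay above the 75th percentile and 5 below the median. Its most covered genes were Kcnh2, a repolarising potassium channel, at 57.6%, Hcn4, the pacemaker channel, at 55.4%, and Ryr2, the calcium release channel, at 46.3%. Nppa, the natriuretic peptide of the chambers, had 18.7%. The signalling list was led by Smad6 and Smad7, inhibitors of BMP and TGF-beta signalling, at 76.0% and 56.1%, and Wnt11 at 59.7%. Smad6 had the most covered window of all protein-coding genes, with 63.8% in replicate 1 and 64.0% in replicate 2.

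The lists of the other heart lineages had medians closer to those of random lists and did not pass the test with the replicated list and the 50 kb window. Genes of the second heart field and outflow tract had a median of 13.5% (random lists 5.09%, permutation test, adjusted p = 0.0572) and endocardial and endothelial genes 13.8% (random lists 5.91%, permutation test, adjusted p = 0.0572). Cushion mesenchyme had 11.13% (permutation test, adjusted p = 0.103), smooth muscle and pericytes 15.0% (permutation test, adjusted p = 0.108), epicardium 7.44% (permutation test, adjusted p = 0.730) and neural crest 7.20% (permutation test, adjusted p = 0.544). Single genes in them were broadly marked. Eng and Notch1, expressed in endocardium, had 54.9% and 52.999% of their windows covered, and Plvap had 35.0%. In the outflow tract list Foxc2 had 35.9% and Hoxb1 34.2%. In cushion mesenchyme Prrx2 had 50.2% and Snai1, a driver of the endothelial-to-mesenchymal transition, 40.8%. Cspg4 had 42.4%, Pdgfrb 38.3% and Myl9 34.0% in the smooth muscle and pericyte list. The epicardial genes Msln, Upk3b and Upk1b had 23.3%, 19.0% and 13.5%, and the neural crest genes Plxna2, Sox10 and Ednra had 28.6%, 27.5% and 24.1%. Endocardial and endothelial genes passed in the replicate 1 list (permutation test, adjusted p = 0.0223, with a range of 0.0115 to 0.826 over 12 alternatives). Second heart field genes passed when peaks were counted in place of coverage (permutation test, adjusted p = 0.0357, with a range of 0.00112 to 0.297 over 12 alternatives). With a window of 10 kb, 9 lists passed the test as higher in place of 4, the added ones being second heart field, endocardium and endothelium, cushion mesenchyme, smooth muscle and pericytes, and neural genes.

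No list of marker genes of other organs and blood passed the test, apart from olfactory receptors. The medians, with those of random lists in parentheses, were 4.88% (9.29%) for erythroid genes, 12.4% (8.38%) for macrophage and myeloid genes, 7.53% (9.32%) for lymphoid genes, 7.80% (6.04%) for hepatocyte and foregut genes and 7.995% (4.84%) for neural genes. They were 13.0% (6.37%) for skeletal muscle, 15.3% (6.81%) for limb, 6.03% (5.92%) for pluripotency and germ line, 4.26% (6.29%) for adult epithelial organs and 14.6% (8.41%) for housekeeping genes, and none of these 10 lists passed the permutation test, where the lowest adjusted p was 0.181. Lists of this size leave such gaps open, since the test called only 51.5% of simulated lists of 20 genes with coverage multiplied by 2. That share is for p before adjustment, a looser limit than the adjusted p used here. Olfactory receptor genes, 1134 in number, had a median of 0 against 9.74% for random lists (permutation test, adjusted p = 1.4e-04), and 945 of them had no replicated peak in the window. Against random lists matched on GC content, whose median was also 0, this difference was lost (permutation test, adjusted p = 1.0, with a range of 1.05e-04 to 1.0 over 12 alternatives). Coverage cannot fall below 0, so no list could be called lower there, and the comparison does not decide what GC accounts for. Single genes of the other lists ranged widely. Tnnt3, a fast skeletal troponin T, had 68.7% of its window covered, Rplp0, a ribosomal protein gene, 44.2%, Prox1 34.8%, Lmx1b 32.7%, Cd4 31.3%, Sftpb 28.4%, Nfe2 27.3%, Spi1 27.2%, Stra8 25.9%, Olfr70 25.04% and Tubb3 16.5%. The lowest of each list were Alas2, Adgre1, Cps1, Myh4, Zfp42, Umod and Olfr998 at 0, Hprt at 0.527%, Syn1 at 0.688%, Cd8a at 1.56% and Grem1 at 2.14%. Alas2, Syn1 and Hprt lie on chromosome X.

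The cardiomyocyte lists were tested directly against the others, in comparisons added after the data were examined. The lists joined as cardiomyocyte lists had each already passed the coverage test on the same values. The 65 genes of the transcription factor, sarcomere and conduction lists had a median of 28.2%, against 7.86% for 124 genes of other cell types (permutation test, two-sided, p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 4e-05 over 4 comparisons). They also exceeded the 106 genes of the other heart lists, with a median of 12.2% (permutation test, adjusted p = 4e-05). These 106 genes included the signalling list, which had passed the coverage test. The 106 genes in turn lay above the genes of other cell types (permutation test, adjusted p = 0.0327). Whether they would do so without the signalling list was not tested. Sarcomere genes at 32.3% exceeded skeletal muscle genes at 13.0% (permutation test, adjusted p = 0.00907). The 4 differences had the same direction and passed the threshold in the list of each replicate.

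A peak close to the TSS was common to most genes. Within 2 kb of the TSS, 66.3% of protein-coding genes (14406) had a replicated peak. All 23 sarcomere genes had one (Fisher's exact test, two-sided, adjusted p = 9.81e-04), as did all 21 signalling genes (exact test, adjusted p = 0.00183), 21 of 22 endocardial and endothelial genes (exact test, adjusted p = 0.0128) and all 12 smooth muscle and pericyte genes (exact test, adjusted p = 0.0399). The call for smooth muscle and pericyte genes was lost at a −log10 q of at least 5, in the pooled list, in the replicate 1 list and with a 5 kb window (exact test, adjusted p = 0.104, 0.0598, 0.0505 and 0.0702, with a range of 0.0201 to 0.104 over 7 alternatives). At the q limit 11 of 12 had a peak. In the pooled list, the replicate 1 list and the 5 kb window all 12 still did, against 72.1%, 67.4% and 70.3% of other genes. The cardiac transcription factors, at 17 of 22 (77.3% against 66.3% of other genes), were not called (exact test, adjusted p = 0.430). Neural (16 of 18), limb (9 of 10), housekeeping (14 of 16) and skeletal muscle genes (12 of 15) were also higher but not called. Neural genes passed with windows of 1 and 5 kb (exact test, adjusted p = 0.0434 and 0.0128). Housekeeping genes passed in the pooled list (exact test, adjusted p = 0.0326). The remaining lists outside the heart lay below other genes. Fewer macrophage and myeloid genes had a peak within 2 kb, 3 of 12 (exact test, adjusted p = 0.0176). This call was lost in the replicate 1 list, in the pooled list and with a 5 kb window, where 6 of 12 had a peak (exact test, adjusted p = 0.312, 0.160 and 0.302, with a range of 4.04e-04 to 0.312 over 7 alternatives). Only 14 of 1134 olfactory receptor genes had a peak within 2 kb of the TSS, which is 1.23% against 69.9% of other genes. The exact tests of all lists were matched on neither gene density nor GC content, and the coverage call of signalling genes was lost against random lists matched on GC. For olfactory receptors that coverage comparison could not call a lower value, so what GC accounts for stays open.

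Long stretches of H3K4me1 gathered at the genes of 5 of the 10 heart lists. Peaks separated by up to 3 kb were merged into 69296 domains with a median length of 1359 bp. The longest 5%, 3466 domains of at least 12302 bp, held the TSS of 1842 protein-coding genes, which is 8.48%. They held the TSS of 16 of 23 sarcomere genes (Fisher's exact test, adjusted p = 9.69e-12), 9 of 22 cardiac transcription factors (exact test, adjusted p = 2.79e-04), 8 of 21 signalling genes (exact test, adjusted p = 0.00103), 7 of 18 second heart field and outflow tract genes (exact test, adjusted p = 0.00180) and 6 of 20 conduction and calcium genes (exact test, adjusted p = 0.0177). The second heart field call was lost with a smaller merging gap of 1 kb and with the larger one tried (exact test, adjusted p = 0.722 and 0.676, with a range of 3.52e-04 to 0.722 over 8 alternatives), that of the transcription factors with a gap of 1 kb (exact test, adjusted p = 0.461, with a range of 1.86e-06 to 0.461), and that of conduction genes at a −log10 q of at least 5 (exact test, adjusted p = 0.126, with a range of 0.00546 to 0.126). The other 5 heart lists were not called: cushion mesenchyme with 5 of 19 genes, neural crest and smooth muscle with 3 of 12 each, endocardium and endothelium with 3 of 22, and epicardium with 1 of 10 (exact test, adjusted p = 0.0555, 0.175, 0.175, 0.598 and 0.647). Cushion mesenchyme was called in 5 of 8 alternatives and smooth muscle in 3. Lists of other organs were called in 2 settings, hepatocyte and foregut genes with the longest 10% of domains (6 of 15) and limb genes with the larger merging gap (5 of 10). No olfactory receptor TSS lay in a long domain, of 1134 (exact test, adjusted p = 6.79e-44). For every list the exact test was matched on neither gene density nor GC content, and the coverage call of signalling genes was lost against random lists matched on GC. For olfactory receptors that coverage comparison could not call a lower value. The exact test also counts neighbouring genes as separate units.

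The longest domain, 236.1 kb on chromosome 11 (88435304 to 88671410), lay within Msi2, which encodes an RNA-binding protein, and peaks covered 63.4% of it in replicate 1 and 68.3% in replicate 2. A domain of 193.1 kb on chromosome 8 overlapped Gse1 and Gins2. Further domains overlapped Magi1 on chromosome 6 (165.0 kb), Casz1, a zinc finger gene required for heart development, with Pex14 on chromosome 4 (149.7 kb), and Cacna1c, which encodes the cardiac L-type calcium channel, on chromosome 6 (145.8 kb). Tead1 on chromosome 7 (137.2 kb), Prdm16 on chromosome 4 (134.0 kb), Foxn3 on chromosome 12 (131.6 kb), Ssbp3 on chromosome 4 (131.2 kb) and Dab2ip on chromosome 2 (130.7 kb) completed the 10 longest. Of these, the domains at Magi1, Tead1 and Ssbp3 held the 5′-most TSS of a protein-coding gene.

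The 10 peaks with the highest signal values, which are the peak caller's own values, had summits over 2 kb from the 5′-most TSS of every protein-coding gene. All but 1 of the summits were intronic. The Rai1 peak itself began within 2 kb of the Rai1 TSS. The highest 2 lay in introns of Ahdc1 on chromosome 4, with signal values of 10.1 (133019141 to 133030372) and 9.48 (133039910 to 133053492), 14.4 kb and 33.6 kb downstream of its TSS. The next lay in an intron of Ypel2 on chromosome 11 (signal 8.96), in an exon of the Gse1 locus on chromosome 8 (8.92, with Gins2 the nearest TSS), and in introns of Dab2ip on chromosome 2 (8.85), Sept9 on chromosome 11 (8.70), Smad7 on chromosome 18 (8.65), Rara, a retinoic acid receptor, on chromosome 11 (8.58), Inf2 on chromosome 12 (8.51) and Rai1 on chromosome 11 (8.50). The summit of the Sept9 peak was 139.6 kb from the nearest TSS when only the 5′-most one of each protein-coding gene is used, that of Gm11733.

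The windows that differed most between the replicates included genes of both directions. Ryr2 had 31.0% covered in replicate 1 and 41.6% in replicate 2, Fam122a 20.0% and 30.6%, Ppargc1a 11.9% and 21.3%, Pakap 33.1% and 42.5%, and Daam1 31.9% and 41.3%. Col4a1 and Col4a2, collagen genes that share a promoter region and hence a window, had 54.1% and 63.7%. Replicate 1 was higher at Foxp4 (41.4% and 31.4%), Fam222a (35.2% and 25.4%) and Hoxb3 (31.4% and 21.7%). Over all genes the median was 4.66% in replicate 1 and 5.19% in replicate 2.

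Sequence motifs of cardiac transcription factors were more frequent at the summits of distal peaks than in random sequence of the same GC content. A total of 133211 windows reaching 100 bp either side of the summit were compared with as many windows outside the pooled peaks. The GATA motif WGATAR occurred in 28.8% of peak windows and 20.5% of background windows, a ratio of 1.41. The ratio was 1.80 for MEF2 (1.55% and 0.860%), 1.86 for the COUP-TF motif TGACCTTT (1.34% and 0.721%), 1.39 for MEIS, 1.38 for NKX2-5, 1.36 for FOX, 1.20 for TEAD and 1.18 for ETS. HAND at 1.08 and SOX at 1.02 were also called. The adjusted p of Fisher's exact test was 4.78e-04 for SOX and 4.63e-21 or below for the other 9. The T-box motif AGGTGT was less frequent in peaks, at 11.8% against 12.9%, a ratio of 0.913 (exact test, adjusted p = 2.14e-18), and so was the SRF motif, with a ratio of 0.917 (exact test, adjusted p = 0.0497, with a range of 2.88e-04 to 1.0 over 10 alternatives). In the replicate lists taken alone, 10 of the 12 heart motifs were called higher in replicate 1 and 9 in replicate 2, where SOX was lost. SOX was also lost in the 25% of peaks with the highest signal. HAND was lost in the 62281 peak windows free of repeats (exact test, adjusted p = 0.613, with a range of 6.77e-72 to 0.613 over 10 alternatives).

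Of the 8 motifs of other tissues, HNF4, HNF1, POU5F1-SOX2 and CTCF were not called against the random background, and the P53 motif occurred in 0 windows of both sets. These results depended on the setting. CTCF, with a ratio of 1.12, was called in 5 of 10 alternatives and in both directions, at 1.86 in windows of 250 bp either side and 1.36 in the replicate 1 list, but 0.647 against windows 5 kb away matched on GC. POU5F1-SOX2 was called in 4 alternatives, with ratios from 0.537 to 1.33, and HNF4 in 3, all higher. The muscle E-box CAGCTG, listed for MYOD, had a ratio of 1.41, while NEUROD and SPI1 had 1.08 each, and both were lost in the replicate 2 list. NEUROD changed direction in windows of 250 bp either side (0.980), without repeats (0.987) and against windows 5 kb away matched on GC, where it was called lower (0.948). The choice of background decided some directions. Against windows 5 kb away that were not matched on GC, which averaged 44.2% GC against 52.5% in the peaks, the ratio of GATA fell to 0.911, MEF2 to 0.424, NKX2-5 to 0.958, FOX to 0.882 and SOX to 0.573, and that of TBX5 rose to 1.03. Against windows 5 kb away that were matched on GC, a comparison added after the data were examined, GATA, MEF2, NKX2-5 and FOX were above 1 again, at 1.45, 1.85, 1.37 and 1.41. SRF changed direction to 1.22, and SOX, at 1.01, was no longer called. This GC-matched comparison kept only 80253 of the 133211 peak windows, with a mean GC of 49.8%, so the peaks changed along with the background.

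**Figure D4:**
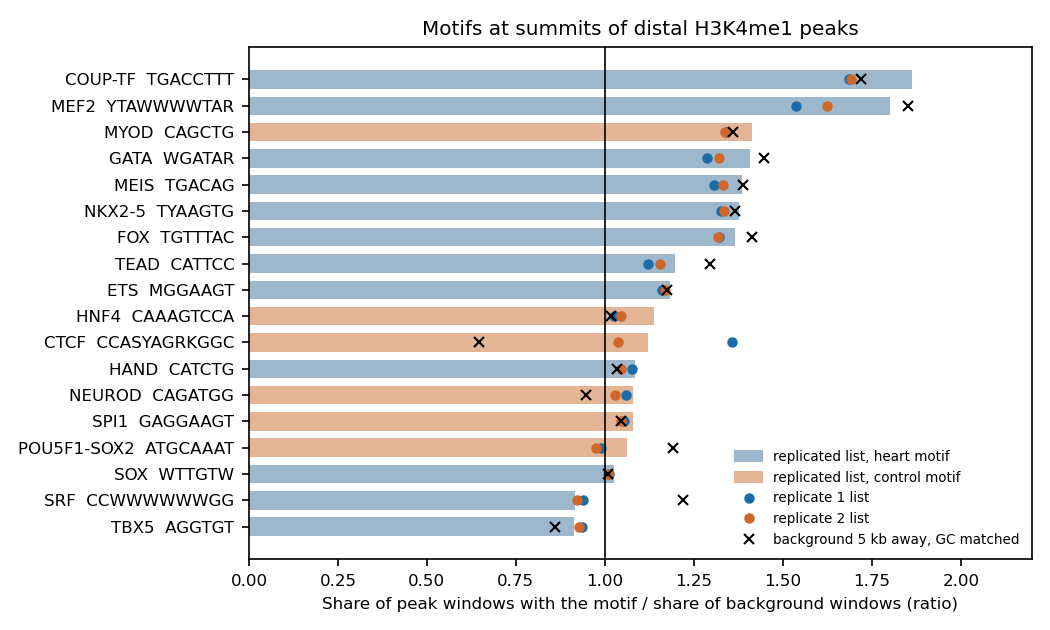
Ratio of the share of distal peak windows with a motif to the share of background windows (horizontal axis, 1 means no difference) for each motif with its sequence (rows). Bars give the replicated list against random GC-matched windows, for heart motifs (blue bars) and motifs of other tissues (orange bars). Blue and orange points give the replicate 1 and replicate 2 lists, and crosses the background 5 kb away matched on GC. COUP-TF and MEF2 have the highest ratios, at 1.86 and 1.80, and TBX5 and SRF lie below 1 in the bars. HNF1 and P53, found in fewer than 10 windows of the replicated list, are not drawn.

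Chromosome X carried few peaks. The replicated list held 617 peaks on X, which is 3.77 per Mb of known sequence, against 64.7 per Mb over the autosomes, where single chromosomes ranged from 49.0 on chromosome 3 to 98.4 on chromosome 11. The autosomal density was 17.1 times that of X in the replicated list, 21.4 times in replicate 1 and 13.2 times in replicate 2. Of the 948 protein-coding genes on X, 96 (10.1%) had a replicated peak within 2 kb of the TSS, against 68.9% of autosomal genes. Leaving out the genes of chromosome X changed no call of the coverage test.

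**Figure D5:**
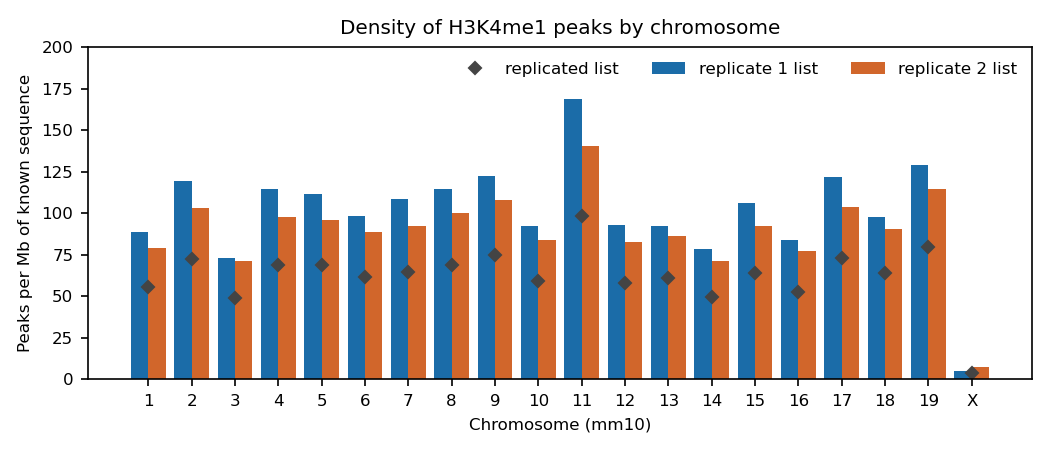
Number of H3K4me1 peaks per Mb of known sequence (vertical axis, from 0) on each chromosome of mm10 (horizontal axis), in the replicate 1 list (blue bars), the replicate 2 list (orange bars) and the replicated list (diamonds). The replicated list ranges from 49.0 to 98.4 on the autosomes and is 3.77 on chromosome X.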

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

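The pooled list held 113125 peaks outside the replicated list, which were not examined on their own above and entered only as part of the pooled list. Among them, 551 (0.487%) were touched by peaks of both replicates, above the 3 that a count of 0 would allow, and were looked at for that reason. That bound is not a chance expectation, which was not computed, so the count shows no excess. A further 30.4% of these peaks were touched by a peak of replicate 1 alone and 26.4% by a peak of replicate 2 alone. The overlap in none of them reached 50% of the pooled peak in both replicates. No explanation was tested.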

How the results depend on the processing

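Comparisons with random lists matched on GC, motif windows free of repeats and the GC-matched background 5 kb away were chosen after the data were examined. No paired analysis was possible because the study has 1 group. Of the values of single lists under an alternative, 243 of 252 for coverage, 134 of 147 for promoter peaks and 154 of 168 for long domains kept their call, as did 151 of 190 for single motifs. Cardiac transcription factors, sarcomere genes and conduction genes passed the coverage test in all 12 alternatives, with a highest adjusted p of 0.00115 (permutation test). Read depth is not given in the sources used here, so what it limits could not be measured. The cause of the changes below was not tested unless stated.

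A −log10 q of at least 5 left fewer peaks by construction, 136901 in the pooled list, 80570 in replicate 2 (74.3 Mb) and 53567 in replicate 1 (48.5 Mb). The share of replicate 1 peaks overlapped in replicate 2 was 69.4% at a −log10 q of at least 2, 79.0% at 5, 58.9% with an overlap of 50% of the peak, 35.6% with 50% of both peaks, 71.3% with the top 222855 peaks of each list and 66.4% with the top 50000. The share of replicate 2 peaks was, in the same order, 66.5%, 49.9%, 55.5%, 40.3%, 65.5% and 60.7%.

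The ratio to the genome of promoter peaks was 4.28 at a −log10 q of at least 5, 3.38 in the pooled list, 4.79 with a 1 kb window and 2.63 with 5 kb. The intergenic ratio was 0.505, 0.543, 0.525 and 0.498 in the same order, and the intron ratio 1.37 with 1 kb and 1.27 with 5 kb. In the lists of single replicates the promoter ratio ranged from 3.83 to 3.89, the intergenic ratio from 0.5001 to 0.504, the intron ratio from 1.32 to 1.35 and the exon ratio from 1.60 to 1.81. All ratios kept their side of 1. Over all TSSs together, the downstream share over that at the TSS ranged from 1.14 to 1.60.

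With a 10 kb window 9 lists had higher coverage. With random lists matched on GC 0 lists had lower coverage, where the olfactory receptors, at a median of 0 like their random lists, could not be called lower. Single replicates gave 4 to 5 lists with higher coverage and 1 with lower, 3 to 5 with more promoter peaks, 1 to 2 with fewer, and 6 to 7 with more TSSs in long domains and 1 with fewer. Only 1 list had fewer promoter peaks in the pooled list and with a 5 kb window. The longest 10% of domains gave 8 lists, 1 of them of another organ, hepatocyte and foregut.

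Against the background 5 kb away without GC matching, 6 heart motifs were higher and 6 lower, and 2 motifs of other tissues were lower. There the ratio turned for GATA (0.911), MEF2 (0.424), NKX2-5 (0.958), TBX5 (1.03), SOX (0.573) and FOX (0.882). With GC matched there the turned ratios of GATA, MEF2, NKX2-5 and FOX were above 1. That setting kept only the 80253 of 133211 peak windows with a partner of the same GC, and lowered their mean GC from 52.5% to 49.8%. Peaks and background thus changed together, so the GC gap is not separated from the loss of peaks. Leaving out repeats kept 62281 peak windows, with the same limit. SRF turned to 1.20 without repeats and to 1.22 against the GC-matched background 5 kb away, where 2 motifs of other tissues were lower. NEUROD turned to 0.980 in windows of 250 bp either side, 0.987 without repeats and 0.948 against the GC-matched background. A single heart motif, 1 in place of 2, was lower at both stricter q limits, in the pooled list, with 250 bp, in the top 25% by signal, without repeats and against the GC-matched background. Single replicates gave 9 to 10 heart motifs higher, 1 to 2 lower, 1 to 4 motifs of other tissues higher and 0 lower.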

Other observations

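Some of the most covered windows belong to genes outside the fixed lists, named here after their values were seen. Zmiz1, which encodes a coactivator, had 75.8% of its window covered by replicated peaks, Zfpm1, a partner of GATA factors, had 73.4% and Smad3, a TGF-beta effector on the same chromosome as Smad6, had 67.8%. Mrpl23 at 75.2% is a neighbour of Tnnt3 on chromosome 7, and their windows overlap.

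Replicated peaks did not always appear in both replicate lists. Both lists touched 79.3% of them, 1 list touched 19.1%, and neither touched 1.61%. The median −log10 q was 9.16, 5.08 and 3.79 in these 3 classes, and the median length 851, 433 and 346 bp.

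The explanations below had their predictions written before their tests. The GC-matched background 5 kb away, the windows free of repeats, the draws of autosomal peaks, the spread among other palindromes and the rule on SEs in the TSS test were chosen after a result was seen.

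Peaks on chromosome X were rare in both replicates. Gene content and GC were argued against as the whole cause: X gene windows had a mean coverage of 0.511%, and autosomal windows matched on TSS number and GC had 8.76 times as much, where the same ratio for single autosomes ranged from 0.815 to 1.26. Missing sequence was argued against only as the loss of long stretches, since 16 of 17 bins of 10 Mb on X (94.1%) held a replicated peak. A bin passed with 1 peak, so sequence or reads lost throughout X were not excluded. The signal exceeded by 1 peak per Mb was on X 0.556 times that of the autosomes in replicate 1 and 0.558 times in replicate 2 (mean 0.557), but 1000 draws of autosomal peaks to the number on X gave 0.611 to 0.670 and 0.635 to 0.698, inside the range of 0.4 to 0.75 predicted for 1 active or present copy of X. Both ratios on X lay below every draw of their replicate, which argues against fewer peaks at full autosomal signal as the whole pattern. Since the draws also fell in the predicted range, the test does not show that the signal was halved. A halved signal stays open beside a caller that treats X differently and beside sequence or reads lost throughout X. X peaks were weaker than autosomal ones, with median signals of 2.65 against 2.79 in replicate 1 and 2.87 against 3.11 in replicate 2.

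More TSSs lay under a peak in replicate 1, by 5.44 points (SE 0.262 across TSSs), nearly all at CpG-rich TSSs, with 11.4 points there and 0.3 at CpG-poor TSSs. With the same number of top peaks the gap was 4.05 points (SE 0.256), 0.744 of its size. A longer peak list was thus argued against as the whole cause. With the same covered length the gap was 6.78 points. That match removed peaks from replicate 2 alone, since replicate 1 covered less, so the gap could not shrink and this value decides nothing. The bound set beforehand for rejection, a gap kept by over 75%, was missed by a little in the first set. The rule applied, that both gaps exceed 50% of the whole by over 2 SE, was chosen after the result was seen. Only the first gap could have failed it. A difference in GC bias between the libraries may contribute, since distal peaks found in replicate 1 alone had 51.6% GC against 49.2% for those in replicate 2 alone, 2.35 points apart. With 1 library per replicate, a biological difference between the pools was not tested.

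The sequence CAGCTG was as enriched in distal peaks as the GATA motif against the random background, at 1.41 each, but less so without repeats, where GATA had 1.39, and against the GC-matched background 5 kb away, where GATA had 1.45. Among 11 other palindromes of 6 bases with the same GC and no CpG, the highest was CTGCAG, at 1.36 against 1.41 for CAGCTG, and at 1.19 against 1.25 without repeats. Against the GC-matched background 5 kb away CTGCAG was higher, 1.38 against 1.36, so CAGCTG did not stand alone. Base composition was argued against as the whole cause, since palindromes of the same composition differed widely, from 0.680 for GGATCC to 1.36 against the random background, while the excess of CAGCTG over the highest of them was small, 0.0550 or more in the settings its prediction names. Whether an E-box factor or a sequence feature shared with CTGCAG underlies it was not tested.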
